A study of Mus musculus with 2 samples.

How the data were processed

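Droplet single-cell RNA sequencing with the 10x Genomics 3′ chemistry was applied to cells of pancreatic tumours from KPPC and PPSSC mice, with 1 library per genotype. The number of mice behind each library is not given in the sources used here. The deposited matrices hold UMI counts per gene and cell barcode, not normalised, written by Cell Ranger 7.1.0 per the file headers, on build mm10 per the labels. The deposited barcode and feature lists hold other values, the cell barcodes and the gene identifiers and symbols, in matrix order. Seurat is named in the submitters' processing notes, and its role is not stated. Whether intronic reads were counted is not given in the sources used here. Both matrices list the same 32285 genes. Gene positions came from GENCODE on the same build, which lacked 50 of the gene identifiers.

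Barcodes with fewer than 500 detected genes or more than 15% mitochondrial UMIs were removed. This took 1182 of 6266 KPPC barcodes and 928 of 3648 PPSSC barcodes. Doublets were then called per library with Scrublet at its automatic threshold. Scrublet called 2 of 5084 KPPC cells and 22 of 2720 PPSSC cells. A rate of 0.039% in the KPPC library is far below what this number of cells gives, so the automatic call did not work there. An alternative that removed the cells with the highest scores, at 0.8% per 1000 cells, took out 207 KPPC and 59 PPSSC cells. It was chosen after seeing the data.

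The 5082 KPPC and 2698 PPSSC cells that remained were scaled to 10000 counts per cell, log-transformed and clustered together without batch integration. The steps used 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 0. Clusters were named from marker lists of 18 cell classes, fixed before the data were examined. The name needed at least 3 raised markers. The way a cluster's marker level was computed changed after seeing the data, from summed counts to the mean over cells of log counts, because 6 very rich KPPC cells dominated the sums of cluster 22. The 27 clusters fell into 12 classes, of which 8 had at least 50 cells in both libraries and were compared. A class name followed by "-like" stands for cells that share its markers.

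In each class UMIs were summed per library and expressed in CPM of the class total. Log2 ratios are of PPSSC over KPPC with 10 CPM added to both. A gene was called higher or lower only if the libraries differed at least 2-fold and the exact 95% Poisson intervals did not overlap. No test was possible with 1 library per genotype. A gene list entered with at least 5 members of at least 30 UMIs each, and its median log2 ratio was placed among 10000 random lists of the same size, matched on expression over 20 bins. The percentile describes these 2 libraries and is no test across animals. A range for the median came from 500 bootstrap draws over members with Poisson redraws. The 45 lists were fixed before the data were examined.

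Genes named in the text followed a rule fixed before the data were examined. They have at least 50 CPM in a library, at least 30 UMIs, and at least 20% of their level in the class where they are highest. Of these, the rule takes the largest and smallest log2 ratios, 12 each way in epithelial-like, 8 in fibroblast-like and macrophage/monocyte-like and 5 in other classes. It also takes up to 4 members of each list with the largest absolute ratio, and Kras, Trp53 and Smad4. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T-cell receptor, unnamed and sex-linked genes are left out. The text names part of what the rule gives. The share of a named gene's UMIs that the 5 richest cells of its higher library gave was computed after seeing the data. The shared epithelial cluster as a separate comparison was added after seeing the data.

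The calls were tested on simulated counts with the depth of the epithelial-like comparison. Of 50 genes each, 45 were called at 4-fold down, 45 at 3-fold down, 48 at 3-fold up and 50 at 4-fold up. Of 12937 unchanged genes, 8 were called higher and 2 lower, and 6 of 100 unchanged lists fell outside the middle 95% of random lists. The simulation holds counting error and no variation between cells or animals. In the data, 5 cells gave most UMIs of 12 of 51 named genes in epithelial-like cells. In the shared epithelial cluster they did so for 19 of 28 named genes. The simulated rates do not cover such genes. Alternatives for shares covered gene minimums of 200 and 1000, a 25% mitochondrial limit, doublets kept, resolutions 0.5 and 2, and each library clustered alone. List medians and gene values were run with 1000 genes, doublets kept, resolution 2 and each library clustered alone. They were also run with median-of-ratios scaling, a pseudocount of 1 CPM, a minimum of 100 UMIs, cells weighted equally and 10% of the library profile subtracted as free RNA. For the shared epithelial cluster only this last group of settings was run. Its values have no check by gene minimum, doublet setting or reclustering. Computations used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.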

Results

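Single cells from digested pancreatic tumours of 2 mouse genotypes were profiled by droplet sequencing of transcript 3′ ends with molecular identifiers (UMIs). KPPC mice carry a Cre-activated oncogenic Kras allele and floxed Trp53, the gene of the tumour suppressor p53. PPSSC mice keep wild-type Kras and carry floxed Trp53 and floxed Smad4, the shared mediator of TGF-beta and BMP signalling. In both genotypes Pdx1-Cre acts in the pancreatic epithelial lineage. The comparison asks how tumours that arise without an activated Kras allele differ from those that arise with it. The 2 genotypes also differ in floxed Smad4, so the comparison cannot tell the Kras and Smad4 alleles apart. Each genotype is represented by 1 library, so no difference has a replicate check and no test was made. The KPPC library held 6266 barcodes and 70582443 UMIs, and the PPSSC library 3648 barcodes and 32515381 UMIs. After filtering, 5082 KPPC cells with a median of 9510 UMIs and 2698 PPSSC cells with a median of 9226 UMIs remained. Within several classes the KPPC cells were deeper. Median UMIs were 29002 in KPPC and 10265 in PPSSC epithelial-like cells, and 25518 and 10207 in fibroblast-like cells. They were 18121 and 9228.5 in macrophage/monocyte-like and 12737 and 5112 in endothelial-like cells. B-like (6472 and 7617) and plasma-like cells (27696 and 29980) went the other way. Ranges in brackets are 95% intervals, exact Poisson for summed UMIs and exact binomial (Clopper-Pearson) for shares, and cover counting error only. For the median of a gene list the brackets hold a 95% bootstrap range over members and counting error, then the percentile of the median among 10000 random lists matched on expression. Expression is in CPM of the summed UMIs of a class, and paired values give the KPPC library first ("against" the PPSSC library).

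The genes altered by design were read first, in epithelial-like cells. Kras, a small GTPase upstream of the ERK pathway, stood at 151 CPM (139 to 164) in the KPPC and 63.8 CPM (59.4 to 68.6) in the PPSSC library. Trp53 stood at 26.1 CPM (21.3 to 31.6) in the KPPC and 55.6 CPM (51.4 to 60.02) in the PPSSC library, and Smad4 at 78.5 CPM (70.01 to 87.7) in the KPPC and 87.2 CPM (81.9 to 92.7) in the PPSSC library. The epithelial-like cells of the KPPC library came almost wholly from cluster 8 and those of the PPSSC library mostly from clusters 22 and 26. Cluster 22 had 11 raised epithelial and 11 raised acinar markers, and cluster 26 had 12 and 5. Within cluster 8, the epithelial cluster with at least 50 cells of each library (the shared cluster from here on), Kras stood at 152 CPM (139 to 165) in the KPPC and 88.02 CPM (71.6 to 107) in the PPSSC library, Trp53 at 25.7 CPM (20.7 to 31.4) in the KPPC and 25.5 CPM (17.1 to 36.7) in the PPSSC library and Smad4 at 80.3 CPM (71.3 to 90.1) in the KPPC and 58.1 CPM (44.9 to 73.9) in the PPSSC library. In PPSSC cells of clusters 22 and 26 together Trp53 reached 58.8 CPM (54.3 to 63.6) and Smad4 90.3 CPM (84.7 to 96.2). Across the non-epithelial PPSSC classes compared, Trp53 lay between 51.2 and 87.5 CPM and Smad4 between 31.6 and 95.7 CPM. In mm10 the genes span chromosome 6 from 145216699 to 145250239 on the minus strand (Kras, ENSMUSG00000030265), chromosome 11 from 69580359 to 69591873 on the plus strand (Trp53, ENSMUSG00000059552) and chromosome 18 from 73639009 to 73703780 on the minus strand (Smad4, ENSMUSG00000024515). The 3′ tags are not known to lie in the deleted parts, so these values do not check the labels.

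**Figure D1:**
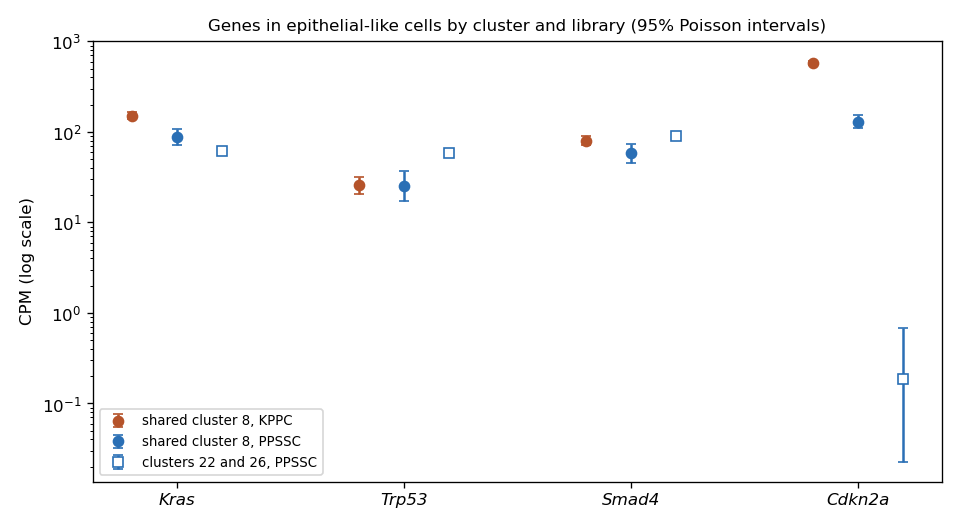
CPM of Kras, Trp53, Smad4 and Cdkn2a (log axis) in epithelial-like cells of the shared cluster 8 in either library and of clusters 22 and 26 in the PPSSC library. Points are values of summed UMIs and bars exact 95% Poisson intervals of counting error; Trp53 is at 25.7 and 25.5 CPM in the shared cluster, and Cdkn2a falls from 579 CPM there in the KPPC library to 0.188 CPM in clusters 22 and 26 combined.

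The tumours differed in their cell make-up. Epithelial-like cells made up 2.09% of KPPC cells (1.71% to 2.52%, 106 cells) and 35.0% of PPSSC cells (33.2% to 36.8%, 943 cells), a 16.8-fold difference. Neutrophil-like cells went the other way, with 17.2% in the KPPC library (16.2% to 18.3%, 876 cells) and 1.37% in the PPSSC library (0.967% to 1.89%, 37 cells). Macrophage/monocyte-like cells held 29.5% and 11.6%, and B-like cells 29.4% and 10.5%, of the KPPC and PPSSC cells. T-like cells held 6.18% and 16.4%, fibroblast-like cells 2.36% and 9.71%, and endothelial-like cells 1.004% and 5.45%. Plasmacytoid dendritic-like cells held 1.89% and 0.445%, plasma-like cells 3.99% and 2.71%, and dendritic-like cells 5.29% and 6.04%. The last 2 depended on the settings: the plasma-like difference of -1.29 points was -3.20 with each library clustered alone, and the dendritic-like one of 0.75 points was 2.45 with 200 genes, 2.72 with doublets kept and 2.70 at resolution 0.5. NK-like cells (33 and 8) and mural-like cells (17 and 16) were few.

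A high share of any class lowers all others, so shares were also taken over the 4976 KPPC and 1755 PPSSC cells outside the epithelial class. On that base neutrophil-like cells held 17.6% (16.6% to 18.7%) against 2.11% (1.49% to 2.89%), and macrophage/monocyte-like cells 30.2% (28.9% to 31.5%) against 17.8% (16.02% to 19.6%). T-like cells held 6.31% (5.65% to 7.02%) against 25.2% (23.2% to 27.3%), and fibroblast-like cells 2.41% (2.00% to 2.88%) against 14.9% (13.3% to 16.7%). Plasma-like cells, at 4.08% (3.55% to 4.67%) against 4.16% (3.27% to 5.20%) in the main clustering, could not be told apart at this depth, but with each library clustered alone 202 KPPC and 21 PPSSC cells were plasma-like. Neutrophil-like cells carry little RNA, with medians of 3468 and 4126 UMIs. With 1000 genes as the minimum their share difference was -14.2 points, against -15.9. The filter removed 18.9% of KPPC and 25.4% of PPSSC barcodes.

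**Figure D2:**
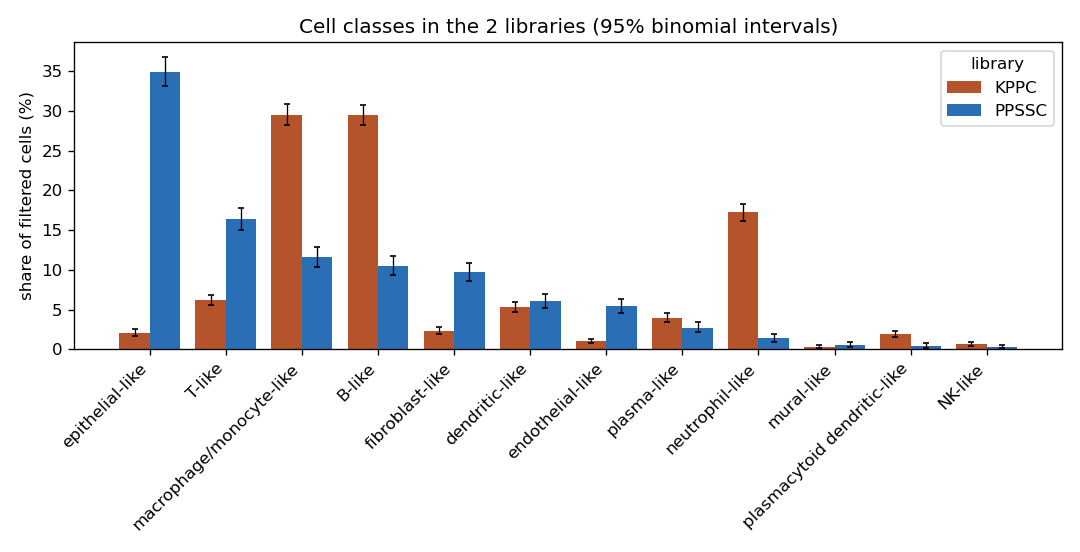
Share of filtered cells in each cell class (percent, linear axis from 0) in the KPPC library (5082 cells) and the PPSSC library (2698 cells), with exact 95% binomial intervals of counting error as whiskers. Epithelial-like cells stand at 2.09% and 35.0%, and neutrophil-like cells at 17.2% and 1.37%.

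Epithelial-like cells of the KPPC library expressed more mesenchymal genes, while ductal and gastric genes went either way. Of the 943 PPSSC cells 884 lay in clusters 22 and 26, and of the 106 KPPC cells 100 lay in cluster 8. Whether the PPSSC cells of clusters 22 and 26 had lost their floxed alleles is not known. Differences over all epithelial-like cells are therefore not shown to be differences between tumour cells. Erbb4, a receptor of neuregulins, stood at 17.2 CPM (13.4 to 21.8) in the KPPC and 1174 CPM (1155 to 1194) in the PPSSC library. Pkhd1, the fibrocystin gene of duct cilia, stood at 45.3 CPM (38.9 to 52.5) in the KPPC and 1383 CPM (1362 to 1405) in the PPSSC library, and Apoe, a lipid carrier, at 370.5 against 6486 CPM. The tight-junction gene Cldn10 (4.05 against 264 CPM), the angiopoietin gene Angpt1 (6.58 against 253 CPM), Fmo2 (11.4 against 654 CPM) and Ces1d (15.7 against 648 CPM) were also higher in the PPSSC library. The digestive protease gene Cym was too, at 5.82 against 679 CPM, with 90.4% of its PPSSC UMIs in 5 cells. The keratin genes Krt7 (900.02 against 159 CPM) and Krt19 (1584 against 806 CPM) of duct cells, chosen after their values were seen, were at higher levels in the KPPC library. In the shared cluster Krt19 went the other way (1675 against 2663 CPM) and Krt7 did not (955 against 370 CPM). Hmga2, an oncofetal chromatin protein, was called higher in the KPPC library, at 347 CPM (329 to 366) against 5.11 CPM (3.90 to 6.57). So was Cdkn2a, which encodes p16 and p19ARF, at 533 CPM (510.04 to 556) against 12.7 CPM (10.7 to 14.9). S100a4 (683 against 7.66 CPM), the fibronectin gene Fn1 (919.5 against 24.2 CPM) and Emp1 (509 against 15.8 CPM) were likewise higher there, as were the gastric peptides Tff1 (1482 against 54.4 CPM) and Gkn2 (361 against 2.30 CPM) and the regenerating-family gene Reg3b (1361 against 21.2 CPM). The 5 richest KPPC cells gave 77.3% of S100a4, 83.4% of Tff1, 99.5% of Gkn2, 70.3% of Reg3b and 39.8% of Fn1 UMIs.

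ERK/MAPK output genes, which read activity downstream of RAS, had a median log2 ratio (PPSSC over KPPC) of -0.34 (-1.17 to 0.31; percentile 0.27). The range includes 0. Of 18 measured members, 8 were lower, 1 higher and 9 not called, and the summed list stood at 3188 against 3571 CPM. The lower ones included Emp1, Phlda1 (339 against 41.5 CPM), Fosl1 (61.8 against 8.85 CPM) and the phosphatase gene Dusp4 (31.1 against 0.851 CPM). The EGF receptor family and its ligands had a median of 0.07 (-1.40 to 0.69; percentile 32.1), with Areg at 149 against 2.21 CPM, Ereg at 47.6 against 0.0851 CPM and Egfr at 109.9 against 34.7 CPM, all lower in the PPSSC library, beside the higher Erbb4. The 5 richest KPPC cells gave 53.7% of Ereg UMIs. Other receptor tyrosine kinases had a median of 1.22 (0.10 to 1.67; above all matched random lists), with 7 of 13 members higher, among them Fgfr3 (16.97 against 169 CPM) and Fgfr1 (40.5 against 222 CPM), and 2 lower, among them Axl (49.9 against 1.36 CPM). In the shared cluster described below this list had a median of 0.09 (-0.63 to 1.13; percentile 52.6). RAS and RAF family genes had a median of 0.21 (-0.36 to 0.35; percentile 55.1), and Kras was the single member called, lower in the PPSSC library.

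TGF-beta/SMAD output genes had a median of -0.63 (-2.06 to 0.22; below all matched random lists); 7 of 19 members were lower and 2 higher. The plasminogen inhibitor gene Serpine1 stood at 156 against 1.19 CPM, Cdkn2b at 129 against 5.19 CPM, and Id1, a BMP target, at 144 against 22.2 CPM. The ligands and receptors of the pathway had a median of -0.01 (-0.44 to 0.50; percentile 8.85), with Tgfb1 at 105 against 9.28 CPM and Tgfbr3 at 3.04 against 43.9 CPM. The mesenchymal program had a median of -1.88 (-3.12 to -0.66; below all matched random lists), 10 of its 14 members being lower, with Vim at 1258 against 89.8 CPM and the repressor gene Zeb2 at 128 against 5.36 CPM. Epithelial junction genes had a median of 0.55 (0.33 to 0.85; percentile 98.9); 6 of 20 were higher and none lower, with Cldn3 at 296 against 880.3 CPM and Cldn7 at 318 against 670.05 CPM. p53 output genes had a median of 0.03 (-0.26 to 0.39; percentile 14.2), with 5 members higher and 3 lower. The 5 richest KPPC cells gave 78.0% of Serpine1, 62.4% of Vim and 69.4% of Zeb2 UMIs. Markers of other cell types, chosen after their values were seen, were also at higher levels in the KPPC library, with Lyz2 at 294 against 63.6 CPM, C1qb at 48.6 against 8.68 CPM and S100a9 at 182 against 18.3 CPM. The stress list moved with these changes, at 1.25 (0.29 to 1.82; above all matched random lists), 11 of its 18 members being higher, but stood at 0.03 (-0.27 to 0.78; percentile 62.7) in the shared cluster.

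Glycolysis and hypoxia genes had a median of -1.03 (-1.46 to -0.34; below all matched random lists); 10 of 19 were lower, such as the hexokinase gene Hk2 (104 against 7.32 CPM), Pkm (529 against 82.7 CPM) and Car9 (53.4 against 4.68 CPM). Cell cycle genes had a median of -0.68 (-0.83 to -0.26; below all matched random lists), with 10 of 19 lower, including Mki67 (32.4 against 8.94 CPM), of which 5 KPPC cells gave 93.8% of UMIs. The mTORC1/MYC list had a median of -0.34 (-0.61 to -0.15; percentile 0.45), with Ldha at 419 against 128 CPM. Ductal and progenitor genes had a median of 0.75 (-0.42 to 1.76; percentile 99.7), 7 of 15 being higher and 2 lower, with the duct regulators Onecut1 at 18.7 against 295 CPM and Onecut2 at 428 against 102 CPM. In the shared cluster Onecut2 went the other way, at 447.5 against 638 CPM. YAP/TEAD output genes had a median of 0.72 (0.01 to 1.85; percentile 99.5), with Ankrd1 at 41.3 against 572 CPM, but 0.25 (-0.18 to 0.60; percentile 80.8) in the shared cluster, where no member was higher and 1 lower. The basal-like list, at -2.18 (-2.52 to 0.42; below all matched random lists), held members of either direction, with Ly6d at 929 against 56.7 CPM and Krt17 at 0 against 71.1 CPM. Wnt output genes stood at -0.55 (-1.33 to 0.30; percentile 0.28), and neutrophil and monocyte chemoattractants at -0.54 (-1.97 to 0.34; percentile 0.69), with Cxcl5 at 234 against 7.32 CPM (95.2% of KPPC UMIs from 5 cells) and Cxcl1 at 69.9 against 151 CPM. Acinar enzymes had a median of -1.46 (-2.60 to 0.22; below all matched random lists), and 6 KPPC cells of cluster 22 with 93206 CPM of Ctrb1 set the KPPC value of 7797 against 264 CPM. Median-of-ratios scaling moved the log2 ratios by a median over genes of -0.15 in epithelial-like cells, -0.16 in the shared cluster, -0.14 in B-like cells and -0.12 in macrophages. It turned the epithelial medians of p53 output to -0.09 and of the EGF receptor list to -0.12.

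The shared cluster compares epithelial-like cells that grouped together, 100 KPPC and 59 PPSSC cells, 1.97% and 2.19% of the libraries. There the ERK/MAPK output median was -0.92 (-1.28 to -0.36; below all matched random lists), and 10 of 18 members were lower and none higher, with the summed list at 3288 against 1499.9 CPM. Emp1 stood at 546 CPM (522 to 571) in the KPPC and 93.3 CPM (76.4 to 113) in the PPSSC library, Dusp6, a phosphatase that ERK induces, at 103 CPM (93.00 to 114) in the KPPC and 22.01 CPM (14.2 to 32.5) in the PPSSC library, and Ier3 at 733 CPM (705 to 761) in the KPPC and 185 CPM (161 to 212) in the PPSSC library. The mesenchymal median was -1.83 (-3.20 to -1.09; below all matched random lists), with 11 of 13 members lower; Vim stood at 1365 against 39.6 CPM and the transcription factor gene Twist1 at 80.8 against 0.880 CPM. C1qb (52.4 against 1.76 CPM) and S100a9 (198 against 8.80 CPM) were lower too, and Lyz2 was not (318 against 426 CPM). TGF-beta/SMAD output, at -0.86 (-1.49 to 0.18; below all matched random lists), had 7 of 16 members lower, 1 higher and 8 not called, and a range that includes 0, with Serpine1 at 169.7 against 0.880 CPM and Id3 at 54.6 against 2.64 CPM. Erbb4 remained higher in the PPSSC cells (18.8 against 679.5 CPM), and Areg (163 against 22.01 CPM) and Ereg (51.9 against 0.880 CPM) lower. Fgfr1 was lower there (38.1 against 9.68 CPM), against its direction over all epithelial-like cells, but its log2 ratio was 0.18 with cells weighted equally. Apoe, Ankrd1 and Cxcl1 also turned, with log2 ratios of -1.55, -0.56 and -1.56 in the shared cluster. Cdkn2a stood at 579 CPM (555 to 604) and 129 CPM (109 to 152). The 5 richest KPPC cells gave 62.6% of Vim, 78.2% of Serpine1, 66.6% of Twist1, 66.7% of Fgfr1, 55.6% of Id3 and 53.7% of Ereg UMIs, and the 5 richest PPSSC cells 51.3% of Erbb4 UMIs.

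Secretory genes separated the shared cluster further. Mucins and goblet genes had a median of 1.70 (1.07 to 2.34; above all matched random lists), with 8 of 10 members higher, and Muc6, the mucin of gastric glands, at 9.38 against 1266 CPM, with 91.0% of its PPSSC UMIs in 5 cells. Tff2, chosen after its values were seen, stood at 2269 against 9262 CPM, against 2112 against 989.6 CPM over all epithelial-like cells. The classical PDAC program, at 0.55 (-1.22 to 1.15; percentile 99.94), had 7 members higher and 6 lower, with Cldn18 at 37.2 against 705 CPM, Anxa10 at 132 against 984 CPM and Gkn1 at 158 against 0 CPM. Over all epithelial-like cells both lists had the opposite sign, with medians of -0.24 and -1.13. Pgc, the gastric pepsinogen C gene, stood at 1.66 against 1575 CPM with 80.9% of its PPSSC UMIs in 5 cells, Chil4 at 0.276 against 1265 CPM and Spink4 at 92.2 against 5575 CPM. Tuft genes, at 2.61 (1.10 to 3.31; above all matched random lists), had 5 of 6 members higher, and the cells behind these members were not counted. Rgs13, a gene outside that list, was seen in 4 PPSSC cells (0 against 262 CPM). Higher in the KPPC cells were Lgals1 (1712 against 6.16 CPM), the matrix gene Fbln2 (379 against 1.76 CPM), Hmga2 (378 against 17.6 CPM) and Hdac9 (219 against 8.80 CPM). Glycolysis and hypoxia genes stood at -0.64 (-0.96 to -0.27; below all matched random lists) and cell cycle genes at -0.71 (-1.04 to -0.40; below all matched random lists). The shared cluster's PPSSC sum holds 1136065 UMIs, and in both libraries several values rest on few cells: 5 cells of the higher library gave 98.1% of Gkn1, 65.4% of Chil4, 59.2% of Spink4, 58.8% of Fbln2 and 54.6% of Lgals1 UMIs. Likewise, 5 cells gave 55.0% of Anxa10, 53.8% of Cldn18 and 54.3% of Hdac9 UMIs.

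**Figure D3:**
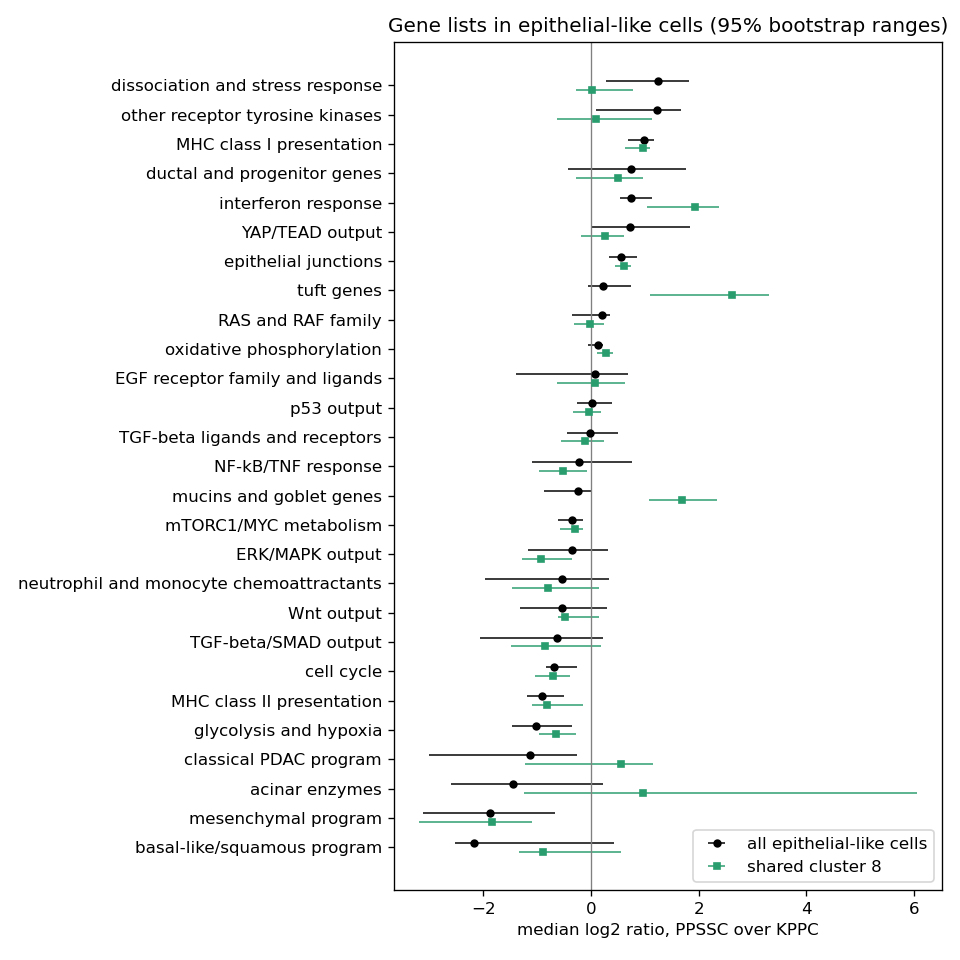
Median log2 ratio (PPSSC over KPPC) of each gene list fixed for epithelial cells, over all epithelial-like cells (circles) and in the shared cluster alone (squares), with 95% bootstrap ranges over list members and counting error as bars. The medians of ERK/MAPK output and the mesenchymal program lie below 0 in both, the ERK/MAPK range over all epithelial-like cells includes 0, and the classical program changes sign between them.

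Fibroblast-like cells of the KPPC library expressed myofibroblastic genes at higher levels than those of the PPSSC library. The KPPC cells lay mostly in cluster 15 (104 of 120) and the PPSSC cells in cluster 16 (255 of 262). The myofibroblastic list had a median of -1.29 (-1.83 to -0.70; below all matched random lists), 11 of 17 members being lower in the PPSSC library, with smooth-muscle actin Acta2 at 367 CPM (347 to 388) in the KPPC and 12.9 CPM (9.12 to 17.7) in the PPSSC library and Tagln at 606 CPM (580.3 to 633) in the KPPC and 50.2 CPM (42.4 to 58.96) in the PPSSC library. The 5 richest KPPC cells gave 66.3% of Acta2 and 60.3% of Tagln UMIs. Fibrillar collagen and matrix genes, at -0.52 (-1.45 to 0.13; percentile 0.89), had 8 of 20 lower, 2 higher and 10 not called, and a range that includes 0, with Col1a1 at 3192 against 809 CPM, Lox at 379.9 against 95.3 CPM and Timp1 at 1008 against 86.1 CPM. TGF-beta/SMAD output in fibroblasts had a median of -0.40 (-0.82 to -0.17; percentile 0.22), with Ltbp2 at 111 against 4.07 CPM and Smad7 at 199.6 against 89.2 CPM. The inflammatory list had a median of 0.43 (-0.37 to 1.001; percentile 98); 6 of 20 members were higher and 2 lower, with Pdgfra at 229 against 699 CPM and Dpt at 519 against 1474 CPM. The antigen-presenting list, at -1.42 (-2.61 to -0.54; below all matched random lists), included Cd74 at 739.9 against 71.9 CPM, while Cd74 stood at 482 CPM in KPPC T-like cells. Markers of other cell types, chosen after their values were seen, moved with it: Lyz2 stood at 447 against 15.3 CPM, C1qa at 87.3 against 6.78 CPM, Cd79a at 32.2 against 9.50 CPM and S100a9 at 71.5 against 11.2 CPM. The MHC class II median in fibroblast-like cells was -2.41, and -0.58 with doublets kept. Other genes higher in the PPSSC fibroblasts were the axon-guidance receptor gene Robo2 (2.09 against 292 CPM), Bmp4 (17.3 against 280.1 CPM) and Adamtsl3 (11.03 against 304 CPM). Hp (1111 against 2.71 CPM), Serpina3n (608 against 36.6 CPM) and Chl1 (274 against 5.09 CPM) were higher in the KPPC ones. The 5 richest KPPC cells gave 52.8% of Hp UMIs. Cfd, the adipsin gene of fat cells, at 1165 against 0 CPM, took 96.0% of its KPPC UMIs from 5 cells.

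Macrophage/monocyte-like cells of the PPSSC library expressed more interferon-response and antigen-presentation genes, and those of the KPPC library more of some monocyte and alternative-activation genes. Clusters 1, 4 and 6 held most KPPC cells (632, 331 and 429 of 1501) and clusters 25 and 17 most PPSSC cells (197 and 82 of 312). Cluster 25 had 12 raised macrophage/monocyte and 8 raised acinar markers. Interferon-response genes had a median of 1.72 (1.48 to 2.002; above all matched random lists); 20 of 23 members were higher, such as Irf7 at 7.16 CPM (6.22 to 8.20) in the KPPC and 118 CPM (107 to 131) in the PPSSC library, Ifi44 (3.37 against 124 CPM) and the T-cell attractant Cxcl10 (12.7 against 138 CPM). MHC class I genes, at 1.27 (0.94 to 1.54; above all matched random lists), had 12 of 16 higher, and MHC class II genes, at 1.11 (0.50 to 1.83; above all matched random lists), 8 of 11, with the class II transactivator Ciita at 11.5 against 148 CPM and H2-Eb1 at 1906 against 8428 CPM. Monocyte genes, at -0.60 (-2.59 to -0.11; percentile 0.07), had 5 of 12 lower and 2 higher. The lipid-associated and alternatively activated list, at -0.38 (-0.88 to 0.11; percentile 0.3), had 6 of 18 lower and 1 higher, and its range includes 0. These lists included thrombospondin Thbs1 at 2188 CPM (2171 to 2205) in the KPPC and 87.7 CPM (77.7 to 98.6) in the PPSSC library, Vcan (177 against 20.4 CPM), Chil3 (424 against 42.7 CPM) and arginase Arg1 (527 against 120.04 CPM), all higher in the KPPC library. The acute-phase gene Saa3 (1074 against 9.11 CPM) and the neuregulin gene Nrg1, an ERBB ligand (349.9 against 24.8 CPM), were also higher there. The resident-macrophage list stood at 0.54 (0.07 to 0.80; percentile 99.99), with Ms4a7 at 59.8 against 376 CPM and Cx3cr1 at 68.1 against 244 CPM. The inflammatory list, at 0.34 (-0.62 to 1.59; percentile 98.8), held Tnf at 52.6 against 185 CPM and Il6 at 100.3 against 13.2 CPM.

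T-like cells of the PPSSC library had more cytotoxic-effector transcripts, more of some naive-cell and less of some regulatory ones. Cluster 7, led by Ikzf2 and Ctla4, held 219 of the 314 KPPC cells, and clusters 24 and 9 held 181 and 170 of the 442 PPSSC cells. Cytotoxicity genes had a median of 1.07 (0.61 to 1.58; above all matched random lists), with 10 of 15 members higher, among them interferon-gamma Ifng at 9.996 CPM (6.74 to 14.3) in the KPPC and 133 CPM (121 to 145) in the PPSSC library, Cd8b1 (35.98 against 152 CPM) and Ccl5 (350.2 against 1180.1 CPM). The 3 lower members included Gzma at 319 against 0.545 CPM, with 99.1% of its KPPC UMIs in 5 cells. Regulatory T genes had a median of -0.68 (-0.94 to -0.30; below all matched random lists), 4 of 12 being lower and none higher, with the IL-33 receptor Il1rl1 at 209 against 51.3 CPM and Areg at 139 against 46.9 CPM. Exhaustion and checkpoint genes stood at -0.43 (-0.89 to -0.04; percentile 0.19), with Tnfrsf9 at 420.5 against 106 CPM, Pdcd1 at 144 against 64.4 CPM and Lag3 at 36.98 against 85.9 CPM. Naive and memory genes stood at 0.70 (0.24 to 1.33; percentile 99.99), with 5 of 12 members higher, such as Klf2 (77.3 against 325 CPM) and Sell (20.3 against 75.3 CPM), 2 lower, Satb1 (546 against 212 CPM) and Igfbp4 (31.7 against 15.5 CPM), and 5 not called. The type 17 list stood at -0.65 (-1.14 to 0.14; percentile 0.05), with Il17a at 15.3 against 1.64 CPM, seen in 5 KPPC cells. Markers of other cell types, chosen after their values were seen, were lower in the PPSSC T-like cells as well, with S100a9 at 102 against 16.1 CPM, Lyz2 at 123 against 22.9 CPM, C1qb at 50.6 against 4.64 CPM and Cd79a at 56.3 against 1.09 CPM. With doublets kept the cytotoxicity median was 0.60, and with the top doublet scores removed 0.53.

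In endothelial-like cells, venous and activated genes had a median of -0.90 (-1.89 to -0.50; below all matched random lists), with E-selectin Sele at 172 CPM (146 to 202) in the KPPC and 27.8 CPM (18.00 to 41.1) in the PPSSC library, Ackr1 at 140.5 against 25.6 CPM and Lrg1 at 729 against 219 CPM, all higher in the KPPC library. The 5 richest KPPC cells gave 96.7% of Sele, 95.9% of Ackr1 and 52.98% of Lrg1 UMIs. Macrophage transcripts, chosen after their values were seen, moved the same way in this class, with C1qa at 306 against 2.22 CPM, C1qb at 335 against 4.45 CPM and Lyz2 at 975.5 against 32.3 CPM, and 5 KPPC cells gave 96.9% of C1qb and 96.4% of Lyz2 UMIs. The tip-cell list stood at -0.13 (-0.69 to 0.26; percentile 14.8), with Esm1 at 19.4 against 194 CPM and Nid2 at 152 against 55.6 CPM. Rbp1 (793 against 54.5 CPM) and Col18a1 (359.8 against 24.5 CPM) were higher in the KPPC cells and Siae (9.14 against 199 CPM) in the PPSSC cells. Here 5 cells of the higher library gave 72.4% of Esm1, 65.4% of Nid2, 60.2% of Rbp1 and 56.2% of Col18a1 UMIs. Glycam1, a ligand of high endothelial venules, was at 31.98 against 5966 CPM, and 2 PPSSC cells gave all its UMIs. The class held 51 KPPC and 147 PPSSC cells, all of cluster 0.

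B-like cells of the KPPC library lay mostly in cluster 5 (1186 of 1496) and those of the PPSSC library in cluster 3 (234 of 283). The KPPC cells had more of the chromatin organiser Satb1 (1138 against 345 CPM) and the antiviral deaminase Apobec3 (108 against 16.6 CPM), and the PPSSC cells more Fgl2 (6.82 against 100.5 CPM) and Ms4a6c (21.7 against 198 CPM). Dendritic-like cells lay mostly in cluster 11 in the KPPC library (163 of 269) and in clusters 19 and 14 in the PPSSC library (70 and 59 of 163). The PPSSC cells had more Cxcl9 (20.03 against 290.2 CPM), and the KPPC cells more Ifitm1 (593 against 10.1 CPM), Ccl6 (971 against 54.8 CPM) and Clec4n (245 against 7.88 CPM). Cluster 11 had 5 raised dendritic and 4 raised macrophage/monocyte markers, and Lyz2 (2463 against 647 CPM, chosen after its values were seen) and Fn1 (954 against 39.7 CPM) moved with these genes. The 5 richest PPSSC cells gave 57.9% of Cxcl9 UMIs. Cell cycle genes in dendritic-like cells had a median of -0.93 (-1.23 to -0.54; below all matched random lists), but with doublets kept it was 0.56. Plasma-like cells, mostly of cluster 12 in both libraries (131 of 203 and 52 of 73), differed in Slpi (16994 against 4371 CPM) and Ebf1 (971 against 203 CPM), both higher in the KPPC library. Cluster 12 had 7 raised plasma and 6 raised B markers, and Top2a, Mki67 and Pclaf were among its leading genes. With each library clustered alone 21 PPSSC cells were plasma-like.

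Interferon-response genes had a positive median log2 ratio in all 8 classes compared. The median log2 ratios were 0.76 in B-like, 0.42 in T-like, 1.11 in dendritic-like, 0.97 in endothelial-like, 0.75 in epithelial-like, 0.37 in fibroblast-like and 0.85 in plasma-like cells, beside 1.72 in macrophages; percentiles among matched random lists ran from 98.7 in fibroblast-like cells to 100. In the shared cluster the median was 1.92, with 15 of 17 members higher and Isg15 at 1.38 against 143 CPM, 93.2% of its PPSSC UMIs coming from 5 cells. Isg15 did not follow the list in T-like cells (83.3 against 41.7 CPM) and fibroblast-like cells (26.2 against 18.99 CPM). MHC class I genes, which present peptides to CD8 T cells, had medians from 0.58 in T-like to 1.33 in dendritic-like cells, all above at least 99.9% of random lists, but 0.11 in fibroblast-like cells, at percentile 63.3. With doublets kept the dendritic-like median was 0.59. In T-like cells 1 of 16 members was called higher, and in fibroblast-like cells 1 of 15. The heat-shock genes Hspa1a and Hspa1b, which rise with cell stress, were higher in the PPSSC library in each of the 8 classes. Hspa1a went from 28.7 to 445 CPM in B-like cells and from 80.9 to 1031 CPM in macrophages. The stress list that holds them did not rise in every class. Its medians were -0.07 in fibroblast-like cells (percentile 39.4), 0.18 in T-like and 0.18 in dendritic-like cells with ranges that include 0, 0.38 in endothelial-like, 0.57 in macrophage/monocyte-like, 0.88 in plasma-like, 0.97 in B-like and 1.25 in epithelial-like cells.

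**Figure D4:**
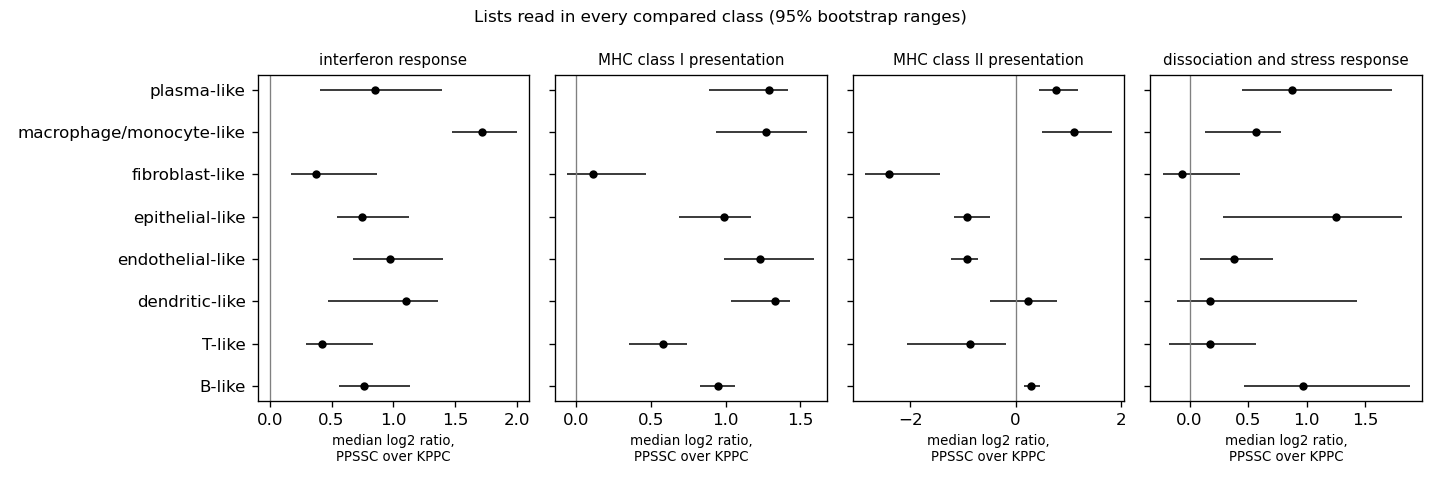
Median log2 ratio (PPSSC over KPPC) of the interferon-response, MHC class I, MHC class II and stress lists in each of the 8 compared classes, with 95% bootstrap ranges over list members and counting error as bars. Interferon medians lie above 0 in all 8 classes, and MHC class II medians range from -2.41 in fibroblast-like to 1.11 in macrophage/monocyte-like cells.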

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

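The tests on sex or strain, on the part of the organ and on floxed alleles, and those by single foreign marker, without fibroblast-like cells and by list member, were chosen after the results were seen. The tests on free RNA, heat shock, the cell filter, cluster makeup and macrophage RNA were written before. The cluster makeup test was read in the shared cluster, a comparison added after seeing the data. Sex-linked genes, outside the comparisons, gave a signal in both libraries: 22006 Y-linked UMIs in the KPPC library against 4 in the PPSSC library, and 25677 Xist UMIs in the PPSSC library against 6 in the KPPC library. Some lists moved in opposite directions in different classes, and these differences were not tested. The MHC class II median was higher by 3.52 in macrophage/monocyte-like than in fibroblast-like cells (1.11 against -2.41), and the fibroblast median was -0.58 with doublets kept. The NF-kB/TNF median was higher by 1.03 in macrophage/monocyte-like than in T-like cells, where S100a9 stood at 102 against 16.1 CPM. The oxidative phosphorylation median was higher by 0.93 in B-like than in fibroblast-like cells.

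Interferon-response medians were positive in all 8 classes, and MHC class I medians ran from 0.58 to 1.33 in all but fibroblast-like cells, at 0.11. With doublets kept the MHC class I median of dendritic-like cells was 0.59 instead of 1.33. The values argue against free RNA at the measured levels, as the interferon list would need at least 40.8% of a class sum. The highest class median of foreign marker levels was 3.08% in the PPSSC library and 9.36% in the KPPC library. In 7 of 8 classes the needed share was above the highest single foreign marker of the same class in the PPSSC library. In T-like, dendritic-like, endothelial-like and macrophage/monocyte-like cells the needed share was set to 100% by rule. The list there stood above its level in the whole PPSSC library. In PPSSC fibroblast-like cells Cd3e reached 212%, where Cd3d was at 3.23%. No foreign marker was an acinar gene, and Clps, a product of acinar cells, stood at 256 CPM in PPSSC macrophage/monocyte-like cells. Free acinar RNA was therefore not measured by these markers. The interferon list stood at 3039 CPM in that class, above the 1307 CPM of the whole PPSSC library. Cells without any Hspa1a or Hspa1b UMI kept on average 95.2% of the interferon median (87.9% without fibroblast-like cells). The median fell in 5 of 8 classes, from 1.11 to 0.53 in dendritic-like (31 PPSSC cells left) and from 0.85 to 0.52 in plasma-like cells (17 left). It rose from 0.37 to 0.83 in fibroblast-like (21 KPPC and 29 PPSSC cells left), 0.97 to 1.18 in endothelial-like and 0.75 to 0.97 in epithelial-like cells. On average the list did not rest on cells with detected heat-shock transcripts. Handling acts on a whole library, and a cell without such UMIs need not have escaped it, so the test cannot exclude handling. MHC class I was not run. Sex or strain background cannot be told apart from genotype, since the 22006 Y-linked UMIs place the libraries in opposite sexes. Genotype itself stays open and untested.

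Epithelial-like cells held 16.8 times the share in the PPSSC library. The cell filter cannot give the whole difference. Counting every removed KPPC barcode as epithelial brings its share to 20.6% at most, against a PPSSC minimum of 25.8%. The bound settles the direction among deposited barcodes and not the size of the difference. A different part of the organ or dissociation yield cannot be told apart from genotype: fibroblast-like cells, too, were 6.19 times as frequent outside the epithelial class. PPSSC epithelial-like cells that kept their floxed alleles also stay open: Trp53 in PPSSC cells outside the shared cluster stood at 58.8 CPM, inside the 51.2 to 87.5 CPM of non-epithelial PPSSC classes and above the 25.5 CPM of the shared cluster. Smad4 stood at 90.3 CPM outside and 58.1 CPM inside the shared cluster, both within the 31.6 to 95.7 CPM of the non-epithelial classes. Cdkn2a stood at 0.188 CPM outside and 129 CPM inside it. The prediction set the p53 output list at over 0.25 above random lists outside the shared cluster. It lay at 0.26 against a random 0.10, so that part was not met. Cells that kept Trp53 need not raise p53 output genes, so this result does not decide the question.

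In PPSSC epithelial-like cells 10 of 14 mesenchymal genes were lower and 2 higher, and 8 of 18 ERK/MAPK genes were lower and 1 higher; the ERK/MAPK range over all epithelial-like cells (-1.17 to 0.31) includes 0, and its summed list was not lower (3188 against 3571 CPM). Within the shared cluster the ERK/MAPK list lay at -1.01 relative to matched random lists. Different shares of the epithelial clusters therefore do not account for all of that list's difference. The test cannot exclude a different makeup inside the shared cluster. Vim was seen there in 47 of 100 KPPC and 3 of 59 PPSSC cells, and Pgc in 3 of 100 KPPC and 18 of 59 PPSSC cells. These cell counts are not at equal depth, as the medians in that cluster were 27502 KPPC and 17294 PPSSC UMIs. Free RNA of macrophages does not account for the 18 lower members of the 2 lists: each would need at least 8.31% of the macrophage level, and Lyz2, C1qa, C1qb and C1qc reached at most 2.47%. These 4 also reached a median of 0.0673 of the level that Fn1, a mesenchymal gene, would need. The biological reading, a difference that goes with genotype, is a hypothesis from the same data. Kras and floxed Smad4 differ together between the genotypes and cannot be told apart. With 1 library per genotype the reading was not tested against sex or differences between animals.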

How the results depend on the processing

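The removal of the top doublet scores and the shared cluster alone were tests chosen after seeing the data; the rest were planned. No paired analysis was possible because each genotype has 1 library. Of 94 alternative share values, 86 stayed within the counting interval and 8 moved. Of 1044 list medians, 976 stayed within their range, 58 moved and 10 reversed. Of 1508 gene values, 1007 stayed within the counting interval, 495 moved and 6 reversed. A gene was counted as reversed only if its sign changed and it had been called higher or lower. For Kras, Trp53 and Smad4 the interval of the ratio had to exclude equality instead. Endothelial-like cells were too few with 1000 genes (45 KPPC) and with top doublet scores removed (41 KPPC), and plasma-like cells with 1000 genes (47 PPSSC) and clustered alone (21 PPSSC), so these gave no value. For every value below the cause was not tested.

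Share differences in points: with 200 genes the dendritic-like one was 2.45 against 0.75, with doublets kept 2.72 and at resolution 0.5 2.70; at resolution 0.5 macrophage/monocyte-like was -19.9 against -18.0; with 1000 genes neutrophil-like was -14.2 against -15.9; clustered alone, NK-like was -0.67, epithelial-like 28.6 and plasma-like -3.20.

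Median-of-ratios scaling gave 0.74 for MHC class I, 0.0735 for MHC class II and 0.25 for oxidative phosphorylation in B-like cells, 0.0676 for oxidative phosphorylation in plasma-like and -0.0759 in epithelial-like cells, 0.67 for Trp53 and -0.0648 for Smad4 in epithelial-like cells, and 0.43 for junctions, -0.65 for Wnt output and 0.0674 for oxidative phosphorylation in the shared cluster. A pseudocount of 1 CPM gave interferon medians of 1.18 in B-like, 1.39 in dendritic-like, 1.66 in epithelial-like, 3.16 in macrophage/monocyte-like cells and 3.27 in the shared cluster, cell cycle medians of -1.73 in dendritic-like, -1.03 in epithelial-like, -1.80 in fibroblast-like cells and -1.05 in the shared cluster, MHC class II of -2.06 in T-like cells, MHC class I of 1.26 in epithelial-like cells, and -3.40 for the mesenchymal program and 3.74 for tuft genes in the shared cluster.

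Cells weighted equally gave -0.97 for regulatory T genes, -1.41 for MHC class II in endothelial-like cells, 0.0249 for NF-kB/TNF (reversed) and -0.85 for Kras in epithelial-like cells, -0.46 for cell cycle in fibroblast-like cells, and 0.0270 for MHC class II (reversed), 0.10 for oxidative phosphorylation and 0.18 for Fgfr1 (reversed) in the shared cluster. Subtracting 10% free RNA gave MHC class II medians of 0 in T-like, epithelial-like and shared cluster cells, -1.63 in endothelial-like and -0.95 in fibroblast-like cells, -0.36 for stress in T-like cells and 0.21 for NF-kB/TNF (reversed) in epithelial-like cells.

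With 1000 genes the dendritic cell cycle median was -0.0208. With doublets kept, cytotoxicity in T-like cells was 0.60, dendritic cell cycle 0.56 (reversed), dendritic MHC class I 0.59, dendritic oxidative phosphorylation 0.41, macrophage/monocyte cell cycle 0.93, plasma cell cycle 0.0804, and MHC class II -0.20 in epithelial-like, -0.58 in fibroblast-like and 0.20 in plasma-like cells. Resolution 2 gave cell cycle medians of 0.31 in dendritic-like (reversed), 0.94 in macrophage/monocyte-like and 0.0750 in plasma-like cells, and 0.20 for MHC class II in plasma-like cells. With each library clustered alone, cell cycle was 0.46 in B-like, -1.41 in T-like (reversed), 0.15 in dendritic-like (reversed), -0.98 in epithelial-like and 1.04 in macrophage/monocyte-like cells, oxidative phosphorylation 0.61 in B-like and -0.0168 in T-like cells, and MHC class II -2.53 in endothelial-like and -1.52 in epithelial-like cells. With the top doublet scores removed, MHC class II was -0.16 in T-like and -0.78 in fibroblast-like cells and cytotoxicity 0.53.

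In the shared cluster alone, the epithelial values were 0.55 for the classical program, 1.70 for mucins, 0.97 for acinar enzymes and -0.00539 for Trp53, all reversed, and -0.56 for Ankrd1, -1.55 for Apoe, -1.56 for Cxcl1 and -1.29 for Fgfr1, also reversed. For Trp53 only the sign changed, as it stood at 25.7 CPM in the KPPC and 25.5 CPM in the PPSSC library there. The other epithelial values in that cluster were 0.0867 for other receptor tyrosine kinases, 2.61 for tuft genes, 1.92 for interferon, 0.0260 for stress, 0.27 for oxidative phosphorylation, -0.72 for Kras and -0.41 for Smad4. Depth was lowest in endothelial-like cells, with 875487 KPPC and 898935 PPSSC UMIs, and low in the shared cluster, with 1136065 PPSSC UMIs from 59 cells.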

Other observations

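Within the PPSSC library the epithelial-like clusters 22 (409 cells) and 26 (475 cells) differed from each other in genes chosen after their values were seen. Cluster 22 had 11 raised epithelial and 11 raised acinar markers, a tie, and cluster 26 had 12 and 5. The acinar enzyme gene Ctrb1 stood at 465 CPM (447 to 484) in cluster 22 and 108 CPM (98.99 to 117) in cluster 26. Cluster 22 had more Ankrd1, a YAP target, at 1005 CPM (978 to 1032) against 256 CPM (243 to 270.1) in cluster 26. It also had more of the chloride channel gene Cftr, at 285 CPM (271 to 300.3) against 38.6 CPM (33.5 to 44.2), and of the acinar and ductal regulator Nr5a2, at 184 CPM (172 to 195) against 87.5 CPM (79.7 to 95.8). Cdkn2a had 2 UMIs in the 884 cells of both clusters, or 0.188 CPM (0.0228 to 0.681).

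The pancreatic colipase gene Clps, a product of acinar cells, stood at 1.72 CPM (1.28 to 2.27) in KPPC and 256 CPM (239 to 275) in PPSSC macrophage/monocyte-like cells, beside 443.9 CPM in PPSSC epithelial-like and 35.7 CPM in PPSSC T-like cells. Oxidative phosphorylation genes had a median log2 ratio of 0.45 in B-like and -0.48 in fibroblast-like cells. The NF-kB/TNF list had a median of -0.69 in T-like cells, with 4 of 15 members lower and none higher. Its top members were Il1b, Cxcl2 and Ptgs2, and markers of myeloid cells, chosen after their values were seen, moved with them in T-like cells: S100a9 stood at 102 against 16.1 CPM, Lyz2 at 123 against 22.9 CPM and C1qb at 50.6 against 4.64 CPM.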
